A study of Mus musculus with 2 samples.

How the data were processed

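The samples were 2 libraries of genomic DNA from E14 mouse embryonic stem cells at passage 5, 1 by WGBS and 1 by TAPS. Per the labels' protocols, DNA was fragmented, size-selected, ligated to adapters, converted by bisulfite or by NgTet1 oxidation and pic-borane reduction, amplified by PCR and sequenced in paired-end reads on a NextSeq instrument. The labels do not say whether both libraries came from the same DNA preparation. Per the submitters' processing notes the genome build was mm9 and the tools were Trim Galore 0.4.4, cutadapt 1.5, Bismark 0.19, Bowtie2 2.2.3, BWA 0.7.15, Picard 1.119 and SAMtools. Which tool made which file, how duplicate reads were treated and which positions were filtered is not given in the sources used here. Duplicates that remained, or filters that differed between the libraries, would change depth and level.

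Each deposited file held a line per cytosine of a CpG with 6 columns and no header. The deposited fraction is the level of modification, and the deposited counts beside it are the reads that call the cytosine modified and unmodified. Each fraction equalled modified reads over all reads within 0.0001 in both files (38138376 lines in WGBS, 39713002 in TAPS), so the counts were used for every value. TAPS listed 189921 lines with 0 reads and WGBS 0. Positions were read as mm9, without conversion, and are given counted from 1.

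Neighbouring lines of the plus and minus strand were paired into CpGs and their reads summed. This gave 19511049 CpGs listed on both strands and 981931 listed on a single strand, and 21890 lines that could not be paired were left out. A CpG listed in only one library was given 0 reads in the other. Levels are modified reads over all reads, pooled over the CpGs of a region, with 95% Wilson intervals. To compare coverage at equal totals, TAPS reads were thinned at random to the WGBS total with a fixed seed.

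CpGs with at least 10 reads in both libraries and 10 kb windows with at least 10 CpGs and 100 reads in both were compared by the two-sided Fisher's exact test on modified and unmodified reads, with Benjamini-Hochberg adjustment at 0.05. Windows also needed a difference of 20 percentage points. Correlations carry no p-value, since CpGs, windows and islands are not replicates. That across CpGs was set beside the r that binomial sampling at the observed depths would give. Islands were built from the spacing of the listed CpGs, as merged 500 bp windows with at least 25 CpGs, since they need no annotation. Shores reach 2 kb and shelves 4 kb from an island. Strand values used CpGs with at least 10 reads on each strand, except the split by strand of the nuclear CpGs called higher in TAPS, which did not need that depth. Fisher's exact test was tested on simulated data with the depths of 380590 CpGs of chromosome 19: of 923 calls 10 were false, and with nothing moved there were 0 calls. Both simulated libraries drew independent reads from the same level at every CpG that was not moved. Duplicate reads and a library-wide difference were absent, so these counts give no false-call rate for the actual data.

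The rule for named regions, fixed before the data were examined, took the 3 windows with the largest difference in each direction among those past their threshold. It also fixed gene lists and promoters. The gene annotation in use here is of another mouse build than mm9, so promoter and gene list results are not reported here and regions carry no gene names. In place of promoters, the promoter part of the rule (at least 10 CpGs and 200 reads in both, the 5 largest differences in each direction past the test) was applied to islands. Islands at 30 to 70% in both libraries were named by size, and unmodified stretches (consecutive 1 kb bins with at least 3 CpGs, 20 reads and a level under 15%) by length; both were chosen after the data were examined.

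Alternatives were other read minimums (5 and 20), strands as separate sites, thinning each CpG to the smaller depth, leaving out very deep CpGs (above the 99.9th percentile) or CpGs whose strands differ by 50 points, other window sizes (1 kb and 100 kb) and differences (10 and 30 points), other island densities (35 and 20), means of CpG levels in place of pooled reads, and a test beyond the odds ratio of the libraries over CpGs with 10 reads in both (0.832). Added after the data were examined were strands that differ by 80 points, CpGs with 10 reads per strand in both libraries, and weighting of the WGBS level of each CpG by its TAPS depth over CpGs with at least 1 read in both, which makes both libraries average over the same CpGs; under it the p-values of the unweighted test were kept. At the median depth of 13 reads in WGBS and 19 in TAPS the level of a single CpG near the middle of the scale is uncertain by more than 20 points either way. Values were computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and numba 0.67.0 and drawn with matplotlib 3.10.9.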

Results

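E14 mouse embryonic stem cells, a pluripotent line grown here on gelatin with serum, LIF and the kinase inhibitors PD0325901 and CHIR99021, were profiled at passage 5 by 2 whole-genome chemistries. Whole-genome bisulfite sequencing (WGBS) deaminates unmodified cytosine, so that a cytosine that still reads as C is called modified. TET-assisted pyridine borane sequencing (TAPS) oxidises modified cytosine with the enzyme NgTet1 and reduces the product with pic-borane, so that modified cytosine itself reads as T and no bisulfite is used. Both count 5-methylcytosine and 5-hydroxymethylcytosine together, and the series asks how the bisulfite-free reading describes the genome at single bases. There was 1 library per method, so no difference has a replicate check, and every test on reads compares these 2 libraries and not the methods. The 2 files listed 20492980 CpGs of mouse build mm9 after the strands were paired. WGBS held 263160897 reads over them and TAPS 388303298. Intervals are 95% Wilson intervals and cover counting error only, since PCR reads without molecular identifiers are not independent molecules.

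The stem cell genome was modified at most CpGs in both libraries. Over all CpGs 65.8% of WGBS reads (65.81 to 65.82) and 59.7% of TAPS reads (59.73 to 59.74) called the cytosine modified, a TAPS minus WGBS difference of -6.08 percentage points. TAPS was lower on 19 of 19 autosomes, by -6.75 to -5.60 points, and both libraries put chromosome 11 lowest (62.9% and 56.2%) and chromosome 3 highest (67.9% and 62.2%). The X chromosome stood at 67.9% in WGBS and 62.6% in TAPS, and the Y chromosome at 68.8% and 64.1%. X depth was 0.520 of the autosomal depth in WGBS and 0.513 in TAPS, and Y depth 0.461 and 0.448. Mitochondrial DNA was close to unmodified, at 0.0633% of 938938 WGBS reads (0.0584 to 0.0686) and 0.337% of 1377476 TAPS reads (0.327 to 0.346), and there the direction was opposite, with 217 of 218 CpGs of at least 1000 reads in both higher in TAPS. The libraries covered different CpGs to different depths: with the WGBS level of each CpG weighted by its TAPS depth, an alternative chosen after the data were examined, the levels were 62.9% and 59.9% and the difference was -3.02 points.

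Among the 13510218 CpGs with at least 10 reads in both libraries, levels between 50% and 90% were the rule, with 72.1% of CpGs in WGBS and 75.6% in TAPS. CpGs under 10% made up 5.83% in WGBS and 5.88% in TAPS. Dense DNA is under-represented in these shares: 10 WGBS reads covered 33.6% of the CpGs in CpG-dense islands, against 71.4% of those over 4 kb from them. The libraries parted at the top of the scale, where 12.1% of CpGs reached 90% in WGBS and 6.10% in TAPS, and 2.73% against 0.891% had every read modified. At the other end 4.60% had no modified read in WGBS and 3.98% in TAPS. Shares at these extremes depend on depth, which at these CpGs was 16.6 reads in WGBS and 21.9 in TAPS. Median levels were 72.7% and 69.2%.

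CpG-dense DNA carried little modification in both libraries. The 25465 CpG-dense islands, stretches with at least 25 CpGs per 500 bp and a median length of 912 bp, stood at 12.6% in WGBS (12.55 to 12.59) and 7.02% in TAPS (7.01 to 7.03). The level climbed outside them, from 35.4% and 30.6% in the first 250 bp to 61.0% and 55.3% at 750 to 1000 bp, and reached 66.9% and 61.8% at 4750 to 5000 bp. By density, 1 kb bins with 1 to 4 CpGs stood at 68.1% and 64.4%, bins with 30 to 49 CpGs at 32.4% and 22.8%, and bins with 80 or more CpGs at 1.38% and 1.01%. With the WGBS level of each CpG weighted by its TAPS depth the island levels were 7.71% and 6.94%, a difference of -0.767 points instead of -5.55. In the bins with 80 or more CpGs that weighting turned the direction, to 0.918% in WGBS and 1.03% in TAPS.

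**Figure D1:**
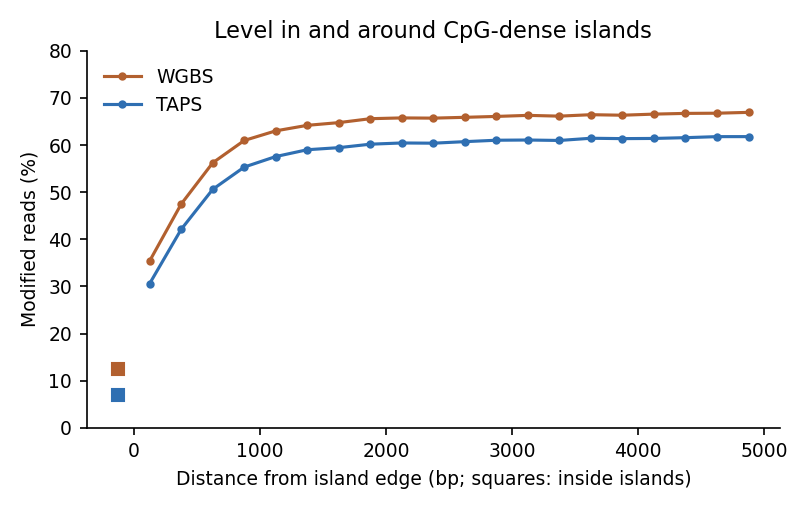
Modified reads (percent) in CpG-dense islands (squares) and in 250 bp steps outside them (lines, distance from the island edge in bp) in the WGBS and TAPS libraries. Both rise from 12.6% and 7.02% inside islands to 66.9% and 61.8% at 4750 to 5000 bp, with TAPS below WGBS at each step.

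Mostly the same islands were unmodified or modified in both libraries. Of the 19327 islands with at least 10 CpGs and 200 reads in both, 13071 were under 10% in WGBS and 13959 in TAPS, and 13011 of these were shared. At 50% or more were 2426 islands in WGBS and 2006 in TAPS, of which 1992 were shared. The same class (under 10%, 10 to 50%, 50 to 90%, 90% and over) held in both for 92.0% of islands, and only 1 island was under 10% in TAPS and at 50% or more in WGBS. Most of that agreement came from the 13011 islands under 10% in both. Of the islands at 10 to 50% in WGBS, 947 were under 10% in TAPS. At 90% and over 0 islands agreed: 74 in WGBS were at 50 to 90% in TAPS, and 10 in TAPS were at 50 to 90% in WGBS. On the X chromosome 338 of 393 tested islands were under 10% in both libraries (86.0%), against 67.0% on the autosomes. X depth was 0.520 of the autosomal depth in WGBS, so the minimum of 200 reads may admit other islands on X, which was not tested. Across islands Pearson's r was 0.987 and Spearman's rho 0.968 (islands are not independent replicates), and the median difference was -0.669 points, or -0.0936 with WGBS weighted by TAPS depth. Most of these islands were under 10% in both. Among the 1992 islands at 50% or more in both the median difference was -6.35 points.

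Levels between 30% and 70% in both libraries were found at 1495 islands, some of them among those at 50% or more. The largest of them, 365 CpGs at chromosome 15, 76006849 to 76012655 (mm9), read 38.5% of 3314 reads in WGBS and 30% of 5110 reads in TAPS. Beside it on chromosome 15, 76004213 to 76006445, an island of 123 CpGs read 63.3% and 52.2%. An island of 143 CpGs at chromosome 7, 53048519 to 53050943, read 62.6% and 48.5%, and one of 142 CpGs at chromosome 5, 140446957 to 140449743, 50.6% and 39.3%. The fifth, of 142 CpGs at chromosome 15, 78502144 to 78504822, read 65.3% in WGBS and 54.7% in TAPS. On weighting by TAPS depth the differences of the largest chromosome 15 island and of those on chromosomes 7 and 5 shrank from -8.53, -14.1 and -11.3 points to -5.19, -5.42 and -6.75. The other two on chromosome 15 moved from -11.0 to -7.77 points (76004213) and, growing, from -10.6 to -12.2 (78502144).

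Long unmodified stretches, runs of 1 kb bins under 15%, were largely shared. Runs of at least 5 kb numbered 473 in WGBS and 572 in TAPS, and 442 of the WGBS runs touched a TAPS run, as 443 of the TAPS runs touched a WGBS run. The longest with both libraries pooled covered 21 kb of chromosome 15, 25681001 to 25702000, with 331 CpGs at 4.49% in WGBS (3.91 to 5.15) and 4.24% in TAPS (3.82 to 4.71). The next, 14 kb of chromosome 16 from 22400001 to 22414000, stood at 3.47% and 3.37%, and 13 kb of chromosome 14 from 64116001 to 64129000 at 2.65% and 2.95%. Runs of 12 kb lay on chromosome 11, 97517001 to 97529000 (1.20% and 1.28%), chromosome 2, 162877001 to 162889000 (2.99% and 2.196%), and chromosome 5, 123582001 to 123594000 (1.11% and 1.02%).

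CpG-dense DNA was read less deeply in WGBS than in TAPS. Relative to the mean of its own library, depth per CpG in islands was 0.614 in WGBS and 0.900 in TAPS, a ratio of 1.47. Shores, the 2 kb beside islands, stood at 0.970 and 0.984, shelves from 2 to 4 kb at 1.007 and 0.986, and the rest of the genome at 1.037 and 1.008. In 1 kb bins with 80 or more CpGs the relative depth was 0.482 in WGBS and 0.931 in TAPS, a ratio of 1.93, whereas in bins with 5 to 9 CpGs it was 1.07 and 1.06. At least 10 reads covered 33.6% of island CpGs in WGBS and 83.0% in TAPS, or 65.6% in TAPS thinned to the read total of WGBS.

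**Figure D2:**
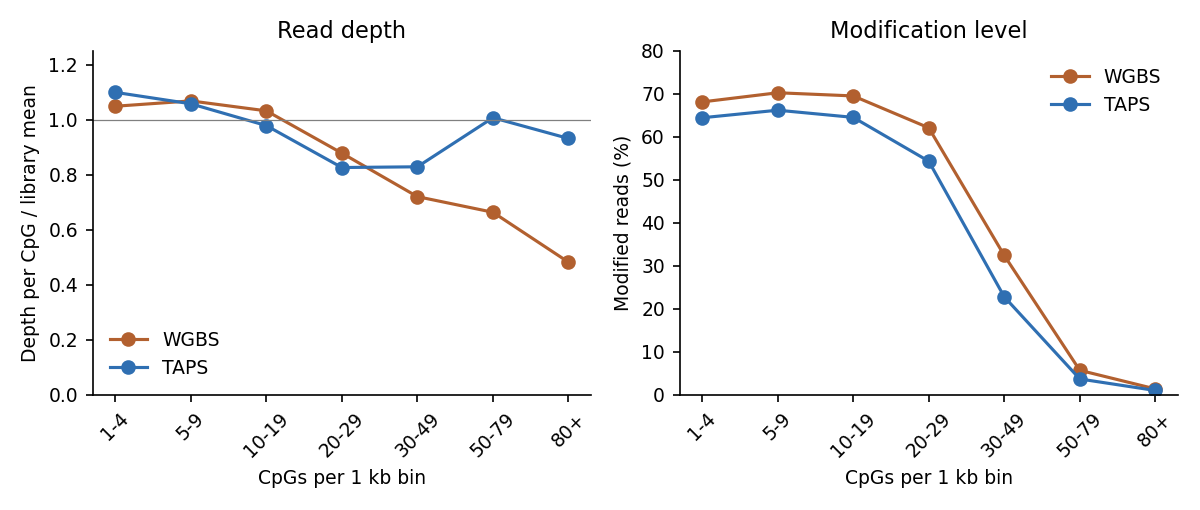
Read depth per CpG divided by the library mean (left) and modified reads in percent (right) by the number of CpGs per 1 kb bin, for the WGBS and TAPS libraries. Relative depth at 80 or more CpGs was 0.482 in WGBS and 0.931 in TAPS, and the level fell from 68.1% and 64.4% in the sparsest bins to 1.38% and 1.01%.

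Over all listed CpGs TAPS was the deeper library, by 1.48 times in mean depth. The mean was 12.8 reads per CpG in WGBS and 18.9 in TAPS, with medians of 13 and 19. CpGs without a read in either library are not among these, so the shares that follow can overstate coverage of the whole genome. At least 1 read covered 97.7% of the listed CpGs in WGBS and 99.0% in TAPS, and at least 10 reads 67.8% and 87.7%. No read covered 470588 CpGs in WGBS and 210755 in TAPS, or 329121 in TAPS thinned to the WGBS total, at which 72.2% of CpGs had 10 reads. At the median depth a CpG near the middle of the scale is known only roughly: 6 modified of 13 reads is 46.2% with an interval of 23.2 to 70.9, and 9 of 19 is 47.4% with 27.3 to 68.3.

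CpG by CpG TAPS lay below WGBS by a mean difference of -3.14 points, and the spread about that mean was little more than counting error. Over the 13510218 CpGs with 10 reads in both, Pearson's r was 0.796 and Spearman's rho 0.595, across CpGs, which are not independent replicates. Binomial sampling of both libraries from the same pooled level would give an r of 0.824, from the WGBS level 0.855 and from the TAPS level 0.835, values that lie too high because the levels drawn from already hold counting error. The difference between libraries had an SD of 14.8 points about its mean, where sampling alone gives 14.5, and 81.9% of CpGs lay within 20 points. After sampling variance was removed, r was 0.987.

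Windows of 10 kb showed the same landscape with less counting error. Across 252968 windows Pearson's r was 0.952 and Spearman's rho 0.878, the median levels were 70.4% in WGBS and 66.3% in TAPS, and 92.9% of windows were lower in TAPS, by a median difference of -4.21 points. With Benjamini-Hochberg adjustment of Fisher's exact test and a difference of at least 20 points, 618 windows were lower and 14 higher in TAPS. Median depth in the 618 windows was low, at 4.93 reads per CpG in WGBS and 8.35 in TAPS against 13.7 and 19.8 over all windows. Very deep windows were over-represented as well. TAPS depth exceeded 2 times its mean in 4.69% of the 618 and 14.3% of the 14, against 0.231% of all windows. With the WGBS level of each CpG weighted by its TAPS depth 183 windows were lower and 12 higher, and the median difference was -3.08 points. The 12 were not all among the 14, since the 3 largest of the 14 fell under the minimum of 20 points.

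**Figure D3:**
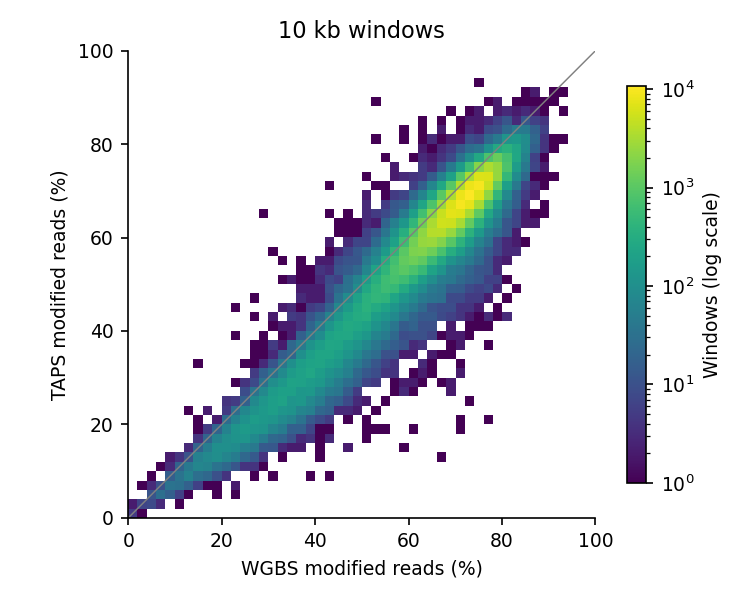
Modified reads (percent) of 252968 windows of 10 kb in WGBS (horizontal axis) and TAPS (vertical axis), with the number of windows per cell on a log colour scale and the line of equal values in grey. Most windows lie below the line, 92.9% of them, with a Pearson's r of 0.952.

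Among the windows lower in TAPS, the largest difference was at chromosome 3, 61960001 to 61970000, with 78.0% of 1579 WGBS reads and 20.2% of 7187 TAPS reads modified. Chromosome 14, 13080001 to 13090000, followed with 67.3% of 168 and 13.5% of 133, and chromosome 18, 85860001 to 85870000, with 71.9% of 884 and 19.3% of 5140. All 3 kept this direction on weighting, at -37.6, -45.0 and -41.0 points. The 3 largest in the other direction were chromosome 2, 150270001 to 150280000, at 28.2% of 850 WGBS reads and 65.6% of 4561 TAPS reads, chromosome X, 39920001 to 39930000, at 53.7% of 149 and 89.0% of 1786, and chromosome 6, 31850001 to 31860000, at 42.5% of 617 and 71.3% of 2616. In all of these 6 windows but that on chromosome 14, TAPS depth exceeded WGBS depth by more than the 1.48 times of the whole libraries. Weighting turned the windows on chromosomes 2 and X to -6.47 and -8.28 points and left the chromosome 6 window at 7.56. Without CpGs whose strands differed by 50 points, the chromosome 2 window stood at 15.4 points, under the minimum of 20.

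Among islands, 144 were lower and 0 higher in TAPS by at least 20 points past the same test. The largest difference was at chromosome 3, 61962462 to 61963466, inside the chromosome 3 window, with 74.4% of 270 WGBS reads and 4.16% of 5627 TAPS reads over 57 CpGs. An island of 25 CpGs at chromosome 7, 137977776 to 137978263, read 46.8% of 252 and 5.37% of 3110, again at very unequal depth. At less unequal depth stood chromosome 9, 49133715 to 49134459 (59.0% of 520 and 13.0% of 208), chromosome 11, 105893299 to 105893728 (61.7% of 243 and 21.4% of 234), and chromosome 9, 17813457 to 17814621 (78.5% of 395 and 39.8% of 299). With WGBS weighted by TAPS depth 114 islands were lower. The chromosome 3 island then moved from -70.3 to -48.2 points and the chromosome 7 island from -41.5 to -59.5, the largest of these 5. The other islands stood at -43.3, -40.6 and -38.8 points. Of the 5 islands furthest above WGBS in TAPS, at 17.6 to 12.8 points, 3 lay on chromosome 12, led by 55875568 to 55876503 (22.7% of 220 reads in WGBS and 40.3% of 720 in TAPS, adjusted p = 3.62e-05 by Fisher's exact test). On weighting by TAPS depth this island stood at 8.89 points and that at 63176559 to 63177382 at 6.43 in place of 15.2, while the others stood at 11.6 to 14.9.

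Single CpGs that differed were few and went mostly the other way from the genome. Fisher's exact test with Benjamini-Hochberg adjustment at 0.05 called 749 CpGs higher and 157 lower in TAPS among 13510218 tested, while 133192 were higher and 328020 lower at an unadjusted p under 0.05. The CpGs called higher differed by a median of 87.5 points, and 8 of them were mitochondrial. Of the 741 nuclear ones, 669 had no modified read in WGBS (90.3%). Their TAPS strands fell into 2 main kinds: 308 had strands that differed by at least 80 points, and 298 stood at 70% or more on both strands. This split includes strands with few reads, since only 354 of the 749 CpGs had 10 TAPS reads on each strand. In simulated data with the depths of chromosome 19 the test called 44.4% of CpGs moved by 60 points and 1.30% of those moved by 30. That simulation adjusted over 380590 CpGs, with 2000 moved by each size and 923 calls in all. Its p threshold was thus less strict than over the 13510218 CpGs, which raises these shares above those of the actual test. Smaller differences at single CpGs were rarely detected at this depth.

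CpGs that read as modified on a single strand were more frequent in TAPS than in WGBS. With at least 10 reads on each strand, the strands differed by 80 points or more, a size chosen after the data were examined, at 17221 of 6449311 CpGs in TAPS (0.267%, 0.263 to 0.271; sampling alone gives 100) and at 65 of 1456069 in WGBS (0.00446%, 0.00350 to 0.00569; sampling gives 29). On the 828505 CpGs with that depth in both libraries the counts were 436 and 34. The high strand was the plus strand at 8539 of the 17221 CpGs and the minus strand at 8682. WGBS read these CpGs at 3.07% on the strand that was high in TAPS and 4.36% on the other, against 64.1% at the remaining CpGs, and 5471 of the 5892 with 10 WGBS reads were under 10% (92.9%). At the 50 points fixed before the data were examined the shares were 0.950% in WGBS and 1.07% in TAPS, a difference of 0.124 points whose sign turned at 5 reads per strand (-0.751), at 30 points (-0.9997) and on CpGs with that depth in both (-0.153).

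**Figure D4:**
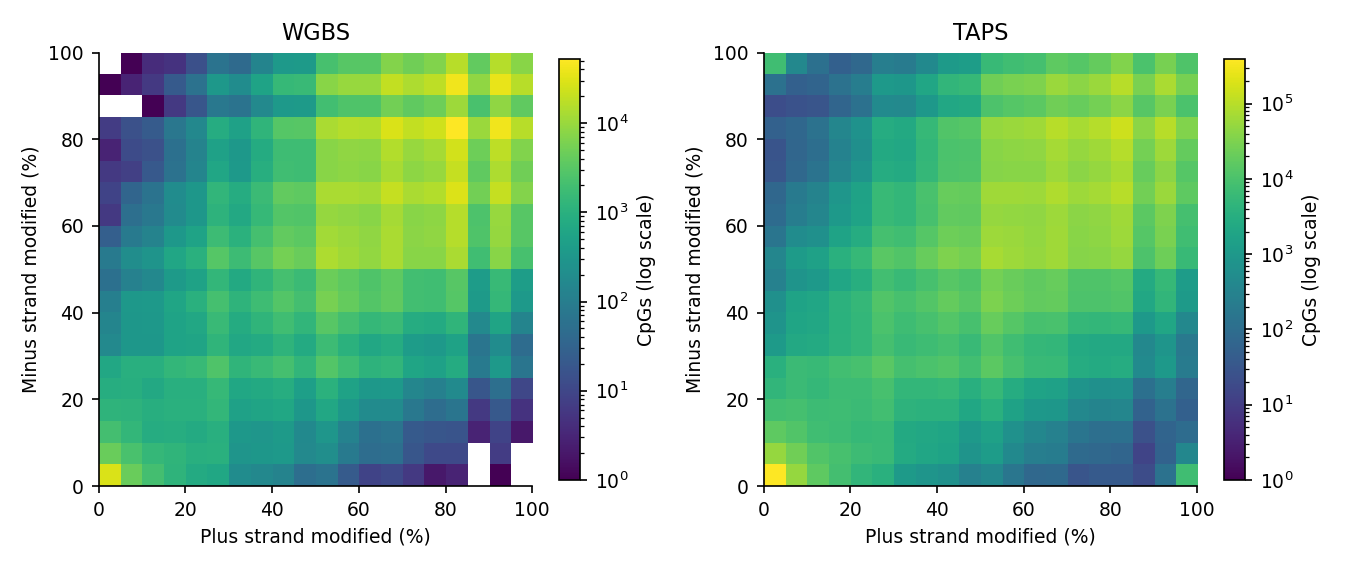
Modified reads (percent) on the plus strand (horizontal axis) and the minus strand (vertical axis) of CpGs with at least 10 reads per strand in WGBS (left, 1456069 CpGs) and TAPS (right, 6449311 CpGs), with the number of CpGs per cell on a log colour scale. TAPS has CpGs in the upper left and lower right corners, where the strands differ by 80 points or more (17221 CpGs, against 65 in WGBS).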

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

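Weighting of the WGBS level by TAPS depth, strands that differ by 80 points, and CpGs with 10 reads per strand in both libraries were chosen only after the results were seen; the other alternatives were fixed before. No paired analysis was possible because there was 1 library per method. Of 71 alternatives 29 kept their direction and side of the threshold or stayed within the counting interval, though some of these differences shrank, such as the chromosome 12 island from 17.6 to 8.89 points on weighting, 35 moved beyond the counting interval or a count beyond 1.5 times, 2 ended a window's call and 5 turned direction. Intervals at this depth are so narrow that small moves count, and the cause of a move was not tested except where the setting itself removes CpGs or reads. Depth limits single CpGs: in simulated data 1.30% of moves by 30 points were called, at a less strict p threshold than in the actual test. The mean depth ratio was 1.47 without very deep CpGs and 1.42 by strand. The TAPS minus WGBS level stayed below 0: -7.04 points as a mean of CpG levels at 10 or more reads, -4.19 on CpGs with 10 reads in both, -6.12 both without very deep CpGs and on autosomes, and -3.02 weighted. The mean of CpG levels used each library's own CpGs of that depth. On CpGs with 10 reads in both it was -3.14 points. Across CpGs r was 0.812 at 5 reads, 0.809 at 20 and 0.702 by strand. The difference in strand disagreement turned to -0.751 points at 5 reads, -0.9997 at 30 points and -0.153 on CpGs deep in both, and was 0.263 at 80 points.

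CpGs called lower and higher in TAPS numbered 95 and 452 at 20 reads and 42 and 364 thinned to the smaller depth, and 1245 were higher beyond the odds ratio of the libraries over CpGs with 10 reads in both. Windows called lower and higher numbered 4342 and 51 at 1 kb, 20 and 0 at 100 kb, 13775 and 148 at 10 points, 69 and 2 at 30 points, and 183 were lower on weighting. Their r was 0.953 at 1 kb, 0.970 at 100 kb, 0.952 without CpGs whose strands differ and 0.965 weighted. On weighting the windows on chromosomes 2 and X turned to -6.47 and -8.28 points. The relative island depth ratio was 1.65 at 35 CpGs per 500 bp and 1.32 at 20. The island level difference was -1.30 and -9.76 points there, -6.22 as a mean of CpG levels at 10 or more reads and -0.767 weighted.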

Other observations

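Chosen only after the results were seen were the tests on all CpGs called higher in TAPS, on CpGs high on both strands, on the ratio of levels over the same CpGs, on the loss of unmodified molecules and on the WGBS level in the densest bins.

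CpGs with opposed strands in TAPS were unevenly spread along the genome. Per 10000 CpGs with 10 TAPS reads on each strand there were 45.9 on chromosome 14 and 44.3 on chromosome 7, against 13.2 on chromosome 10 and 15.8 on chromosome 11. Of 1690 windows of 1 Mb, 419 held none, where an even spread gives 7.26, and the median was 10.6 per 10000 with a 90th percentile of 55.1. WGBS was shallow at these CpGs, with 7.74 reads against 16.4 at the others, while TAPS had 28.7 against 27.2. On the strand high in TAPS the WGBS library had 4.800 reads and on the other 2.94.

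The CpGs called higher in TAPS are a candidate for base differences between E14 cells, which come from another mouse strain than the reference genome, and mm9: a C-to-T substitution reads as modified in TAPS on a single strand and as unmodified in WGBS. Among those called higher by at least 50 points with 10 TAPS reads on each strand, the TAPS strands differed by 50 points or more at 54.8% (49.2 to 60.3), an interval that includes the bound of 50% set beforehand, and among all called higher with that depth at 56.5% (51.3 to 61.6), against 1.07% of all CpGs of that depth. Where both strands were high, here without a need of 10 reads on each, every TAPS read was modified at 94.3% of 298 CpGs (91.1 to 96.4). Substitutions on both strands could give this, while the call itself would select 16.6% from levels spread as at all CpGs at 70% or more in TAPS. The genome sequence of this build was not used here, so no substitution was seen directly, and no biological explanation was tested.

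The lower TAPS level has several candidate sources, and different coverage of CpGs accounts for part of it by construction of the weighting, with 49.7% left on the same CpGs; on CpGs with 10 reads in both 69.0% was left, between the bounds set beforehand. Unconverted cytosines in WGBS, if conversion was alike in all regions, are opposed for the most modified 10 kb windows by 2 low WGBS levels. These were 1.38% in bins with 80 or more CpGs and 0.0633% in mitochondrial DNA. On the same CpGs the difference in the most modified windows equalled 15.1% of the WGBS reads called unmodified. The unconverted share needed there is somewhat smaller, since unconverted cytosines are not among those reads. In the least modified 10% of windows the same value was 2.91%, nearer to 1.38%. The test fixed beforehand stayed open, since mitochondrial DNA gave -0.273 points (WGBS minus TAPS) but islands 5.55. The island difference (TAPS minus WGBS) was only -0.767 on the same CpGs. Loss of unmodified molecules at 1 rate in all windows stays open: on the same CpGs it would give 2.75 points in the most modified windows, which showed 3.52 against 3.24 in the middle ones, but at each library's own depth the difference did not rise, with 4.20 against 4.23 (3.59 under that loss). Incomplete conversion of modified cytosine in TAPS stays open: the TAPS to WGBS ratio in the most modified 10% of windows was 0.946, but the least modified 10% stood at 0.795, while over the same CpGs the ratio ran only from 0.943 to 0.955 and was 0.954 in the most modified 10%, but 0.900 in islands, 0.908 at 30 to 49 CpGs per kb and 1.117 at 80 or more, so a single proportional shortfall does not describe all regions. The ratio of 1.117 rests on 1.03% in TAPS and 0.918% in WGBS, a gap of 0.108 points at very low levels. A true difference between DNA preparations was not tested, and no biological explanation was tested.

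The deeper TAPS reading of islands is not a matter of total depth alone, since a deeper library would have given a ratio of relative depths near 1 and the ratio was 1.47. Base composition, which goes with CpG density, was not tested without the genome sequence, and no biological explanation was tested.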
